A study of Solanum lycopersicum with 2 samples.

How the data were processed

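RNA from leaves of tomato (Solanum lycopersicum) cultivar Moneymaker was profiled in 2 libraries, 1 from control plants and 1 from heat-stressed plants. Per the labels' protocols, plants were 8 weeks old and the heat-stressed plants were moved to a growth chamber at a light intensity of 120 μmol m-2 s-1, held at 39°C for 1 h and returned to 24°C for 1.5 h. The labels do not say whether the control plants were also moved to the chamber or at what time of day they were sampled. The libraries were made by massive analysis of cDNA ends (MACE), in which poly-A RNA is captured and only its 3' end is sequenced. Per the labels' protocols the sequenced part was the last 500 bp of the transcript, with each transcript molecule contributing 1 read. Values therefore need no correction for transcript length, and they depend on whether a gene model reaches the true 3' end of its transcript.

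FastQC is the only tool given by the submitters' processing notes. The aligner, genome build and annotation are not given in the sources used here. Each deposited file lists gene models with their chromosome, strand and identifier. Per the file headers each model has an estimated count of reads, which the authors deposited without normalization and which is fractional where a read was divided between locations. A second deposited column holds the count of all mapped reads of the library, 1 total per file. A further column is called TPM in the header. It equalled the reads of the model divided by all mapped reads and expressed per 1000000 on every row of both files, with a largest difference of 3.42e-08 RPM, so these deposited values are RPM (reads per 1000000 mapped reads), with no term for gene length. Another deposited column gives the height of the highest peak of reads in the model, a signal in reads. How the authors defined a peak is not given in the sources used here. Reads were called whole when at most 0.000001 above a whole number, a peak was called above the reads of its model when it exceeded them by over 0.000000001, and peak heights were called the same when identical as deposited. No identifier was repeated within a file. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense models cannot be told apart.

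The identifiers are not paired with gene names in the files, and 0 of them matched the 41476 genes of the reference table used here. Gene functions were therefore not assigned. The 35 keyword lists fixed before the data were examined (heat shock protein families, co-chaperones, heat stress transcription factors, photosynthesis, ribosomes, hormone pathways, the circadian clock, leaf cell types and others) need gene descriptions, so no list and no share of the library taken by a list was computed. The rule for named genes, which also needs descriptions, was replaced by a shorter one: the 2 models with the highest and the 2 with the lowest log2 ratio past the filter. Other models are described by chromosome, abundance and neighbourhood only. These groupings, and all statements on identifier versions and neighbours, were chosen after the data were seen.

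Models not listed in a library were taken as 0 there. For each model the log2 ratio was log2((heat-stress RPM + 1)/(control RPM + 1)), which understates the change of low models. Models with a mean over both libraries of at least 5 RPM entered the comparison, and those at least 2-fold higher or lower were counted. With 1 library per group no test between conditions was possible, no p-value was computed, and the counts describe these 2 libraries. For single models the ratio of RPM has a 95% conditional exact binomial (Clopper-Pearson) interval and each RPM a 95% exact Poisson interval, both on reads rounded to whole numbers. These intervals cover counting error only and say nothing of the spread between plants, samples or library preparations. Shares of models have exact Clopper-Pearson intervals.

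The median log2 ratio of each chromosome, and its numbers of 2-fold higher and lower models, were set against 10000 random lists of as many models, matched in 10 classes of mean abundance, and given as percentiles. Lists matched also on version were drawn with replacement from the other models of chromosomes 1 to 9. The 12 chromosomes and the unplaced models (chromosome 0) give 13 groups with 3 measures each. Runs of neighbouring models were read from the identifiers, which in this nomenclature number the models along each chromosome. Pairs were consecutive models past the filter, and their number was compared with 10000 shuffles of the calls within chromosomes.

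The depth was 11534512 mapped reads in the control library and 13857252 in the heat-stress library. A single read is worth 0.0867 RPM in the control library and 0.0722 RPM in the heat-stress library, so a model at 5 RPM in both libraries rests on 58 reads in the control library and 69 in the heat-stress library. The calculations were tested on simulated libraries drawn with the real means and depths for the heat-stress against control comparison, with 11274 models past the filter and Poisson noise only. Of 50 models made 3-fold lower 48 were recovered, and of 50 made 4-fold lower 49. All 50 made 3-fold higher and all 50 made 4-fold higher were recovered, and 0 of 11077 unchanged models were called. Alternatives were other pseudocounts (0.1 and 5 RPM), other filters (none and 20 RPM), other scalings (the median ratio, a mean of log ratios with 30% of ratios and 5% of levels trimmed at each end, and the reads in gene models), a 4-fold threshold, and the removal of models with shared reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.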

Results

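The data describe the transcripts of young tomato leaves in 2 MACE libraries, 1 from control plants and 1 from plants that had 1 h at 39°C followed by 1.5 h at 24°C. The control library had 11534512 mapped reads and listed 22893 gene models. The heat-stress library had 13857252 mapped reads and listed 23748 gene models. In the control library 72.5% of mapped reads lay in the listed models, and in the heat-stress library 71.1% did. The series title names the chaperone networks of tomato as the subject. The gene models carry identifiers only, so chaperones and other families could not be picked out by name. There was 1 library per condition, and no difference below has a replicate check.

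The comparison asks which transcripts differed in level between heat-stressed and control leaves. Of 11271 gene models with a mean of at least 5 RPM, 441 (3.91%) were at least 2-fold higher in the heat-stress library and 187 (1.66%) were at least 2-fold lower. The remaining 10643 models lay between. The larger differences were mostly on the higher side: 87 models were at least 4-fold higher and 9 at least 4-fold lower, 30 were at least 8-fold higher and 1 at least 8-fold lower, and 9 were at least 16-fold higher and 0 at least 16-fold lower. The log2 ratios of all models had a median of 0.10 and an interquartile range from -0.17 to 0.37. Scaling both libraries to a median ratio of 1 lowered the heat-stress values by a common factor of 1.08, or 0.11 on the log2 scale before the pseudocount. With that scaling 329 models were 2-fold higher and 262 were 2-fold lower, so the higher models made up 55.7% of the calls in place of 70.2%. All 329 were among the 441, and 186 of the 262 were among the 187.

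The model with the highest ratio was Solyc01g103920.2 on chromosome 1, with 56 reads in the control library and 3807 in the heat-stress library. Its level was 4.85 RPM in the control library (95% Poisson interval 3.67 to 6.30) and 274.7 RPM in the heat-stress library (266 to 284). The ratio of RPM was 56.6 (43.5 to 75.1), and the log2 ratio with the pseudocount was 5.56. The next was Solyc04g014480.2 on chromosome 4, which had 53.3 RPM in the control library and 1661 RPM in the heat-stress library. Its ratio was 31.2 (28.8 to 33.8) and its log2 ratio was 4.94. The model with the lowest ratio was Solyc09g089540.2 on chromosome 9, which had 33.7 RPM in the control library (30.4 to 37.2) and 3.04 RPM in the heat-stress library (2.18 to 4.10). The control level was 11.1 times the heat-stress level (8.06 to 15.6), with a log2 ratio of -3.10. Solyc12g040790.1 on chromosome 12 had 204 RPM in the control library and 30.02 RPM in the heat-stress library. Its control level was 6.81 times the heat-stress level (6.13 to 7.58), with a log2 ratio of -2.73. With a pseudocount of 5 RPM the order was the reverse at both ends, with Solyc04g014480.2 highest at 4.84 and Solyc12g040790.1 lowest at -2.58. Reads of the last 2 models were fractional in at least 1 library, so part of them was divided with other locations.

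**Figure D1:**
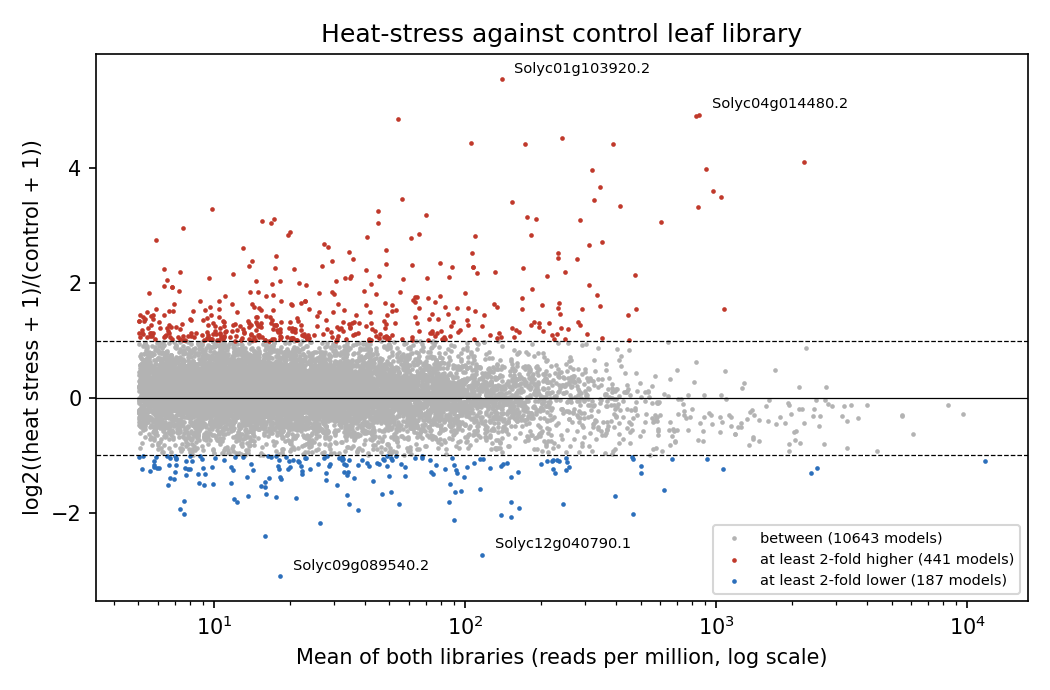
Log2 ratio of the heat-stress over the control library (pseudocount 1 RPM) against the mean RPM of both libraries on a log axis, 1 point per gene model with a mean of at least 5 RPM. Red points mark the 441 models at least 2-fold higher, blue points the 187 at least 2-fold lower, grey points the others, dashed lines the 2-fold thresholds, and the 4 models with the highest and lowest ratios are named.

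Together the 441 higher models held 1.37% of mapped reads in the control library and 5.76% in the heat-stress library, a rise that follows in direction from how they were picked. The 10 models with the largest gains supplied 37.02% of the summed gain of the 441. The most abundant of the higher models, on chromosome 3, was at 242 RPM in the control library, where it ranked 381, and at 4221 RPM in the heat-stress library, where it ranked 7. Its ratio was 17.4 (16.8 to 18.1). There were 11 models under 1000 RPM in the control library and above it in the heat-stress library, from control levels between 52.8 and 909 RPM, and 9 of them were at least 2-fold higher. In the opposite direction 15 models were above 1000 RPM in the control library and under it in the heat-stress library. How many of these 15 were at least 2-fold lower was not counted. The direction of change in both groups follows from how they were picked. In all 79 models were above 1000 RPM in the control library and 75 in the heat-stress library.

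The 187 lower models, picked in the same way, held 4.51% of mapped reads in the control library and 1.94% in the heat-stress library. The most abundant model of the control library was among them. It had 16047 RPM in the control library and 7541 RPM in the heat-stress library, a ratio of 0.470 (0.466 to 0.473), and ranked 3 in the heat-stress library. Of the 100 most abundant control models, 91 had a lower RPM in the heat-stress library, though only 7 passed the 2-fold threshold. This group was picked by its control level, which by itself favours lower values in the other library. The 100 most abundant models of each library held 22.9% of mapped reads in the control library and 18.7% in the heat-stress library. The lists had 80 models in common. Of the 20 models found only in the heat-stress list 13 were at least 2-fold higher, and of the 20 found only in the control list 4 were at least 2-fold lower. Both groups of 20 were picked by their change in rank between the libraries, which by itself favours these directions.

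Differences of 2-fold were spread over all levels of abundance. Among 5 classes of equal size by mean RPM, the share of higher models was 3.50%, 3.68%, 3.19% and 3.50% in the first 4 classes and 5.68% in the most abundant class, which began at 57.7 RPM. The share of lower models was between 0.887% and 1.82% in the first 4 classes and was 2.66% in the most abundant class. These shares are not like for like, because the pseudocount of 1 RPM understates the change of low models. A call in the lowest class therefore needed a larger ratio of RPM than a call in the most abundant class. With a pseudocount of 0.1 RPM, 504 models were higher and 222 lower over all classes, and the shares by class were not recomputed. The median log2 ratio was 0.01 in the most abundant class and between 0.10 and 0.15 in the others.

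The chromosomes differed little in their ratios. The median log2 ratio was highest on chromosomes 7 and 6, at 0.14 and 0.13, and lowest among the placed chromosomes on chromosome 10, at 0.05, with 0.06 on chromosomes 11 and 12. Against random lists of the same size and abundance, chromosomes 10, 11 and 12 lay at percentiles 0.06, 0.26 and 0.315, and chromosomes 6 and 7 at percentiles 98.3 and 97.8. The models of chromosomes 10 to 12 differed from the rest in the version number at the end of their identifiers. Version 2 was carried by 21.04% of the listed models on chromosome 10, 0.421% on chromosome 11 and 0.237% on chromosome 12, against 69.1% to 85.1% on chromosomes 1 to 9. Over all chromosomes the median log2 ratio was 0.05 for the 1964 version 1 models past the filter and 0.12 for the 9307 version 2 models. Of the 1964 version 1 models 1204 lay on chromosomes 10 to 12, so random lists matched on version as well as abundance were drawn from the other models of chromosomes 1 to 9. Against these, chromosomes 11 and 12 lay at percentiles 38.96 and 52.4, well inside their random lists. Chromosome 10 lay at percentile 3.47, chromosomes 6 and 7 at 96.4 and 94.9, and chromosome 2, at percentile 13.5 of the lists matched on abundance alone, at the lower edge of the central 95%. On chromosome 10 the median was 0.06 for version 2 models and 0.02 for version 1 models, against 0.12 and 0.05 on chromosomes 1 to 9. The 52 unplaced models had a median of -0.04, at percentile 2.06 with lists matched on abundance and 1.59 with lists matched on version too. Chromosome 9 had 47 higher models among 883, at percentile 98.3 of its random lists (central 95% of 25 to 46), and chromosome 1 had 18 lower models among 1710, at percentile 0.845 (20 to 39). These were the only 2 of the 26 counts of higher or lower models by chromosome outside the central 95% of their random lists. Among 26 counts, some outside are likely by chance alone. Of the 13 medians, 6 lay outside with lists matched on abundance alone.

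**Figure D2:**
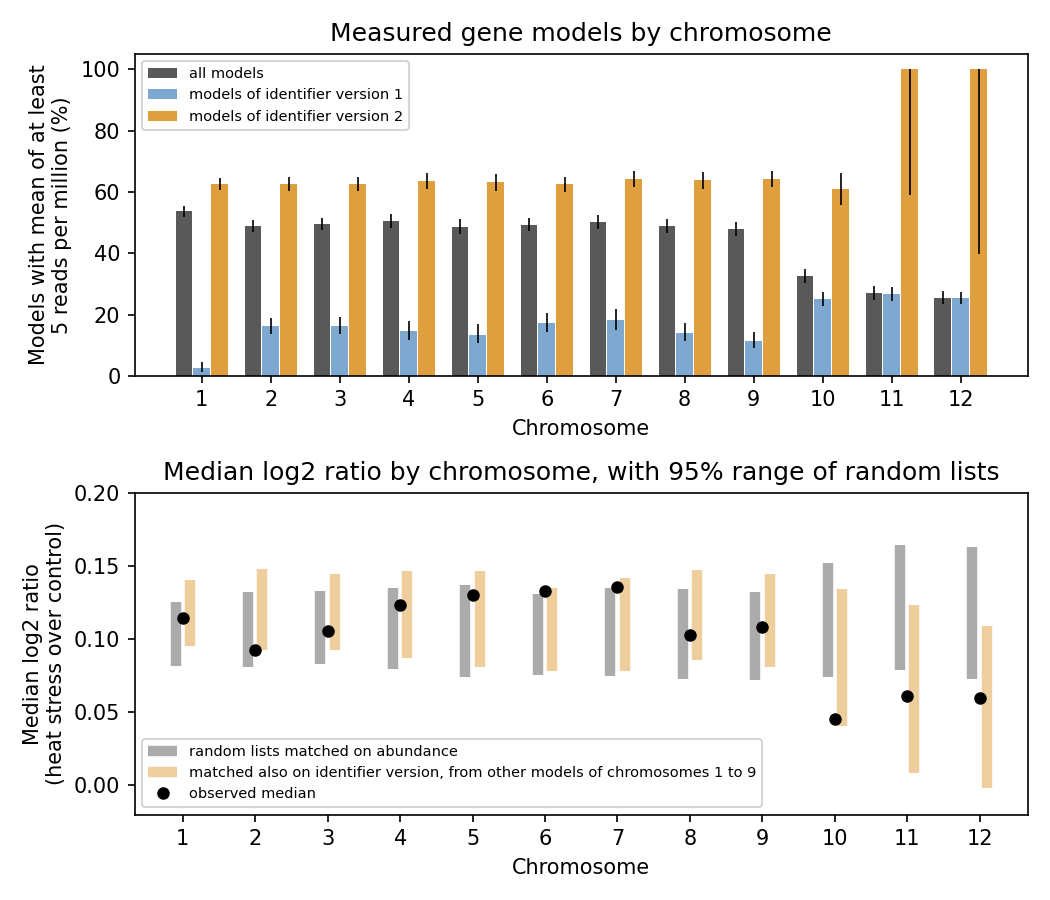
Upper panel, the percentage of listed gene models with a mean of at least 5 RPM on each chromosome, for all models (grey) and for models of identifier version 1 (blue) and version 2 (orange), with 95% exact binomial intervals; all-model values are 25.5% to 32.6% on chromosomes 10 to 12 and 48.0% to 53.7% on chromosomes 1 to 9, and only 7 and 4 version 2 models stand behind the bars of chromosomes 11 and 12. Lower panel, the median log2 ratio of each chromosome (black points) and the central 95% of 10000 random lists matched on abundance (grey), or on abundance and version and drawn from other models of chromosomes 1 to 9 (orange); the points of chromosomes 10 to 12 lie below the grey ranges and inside the orange ones.

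Models at least 2-fold higher followed each other, in identifier order among models past the filter, more often than in shuffled orders. Among the 439 higher models on placed chromosomes there were 35 pairs of consecutive models, where shuffles within chromosomes gave a mean of 17.2 and a central 95% of 10 to 25. The longest run was 4 consecutive models on chromosome 6, lying on 2 strands. Together they had 235 RPM in the control library and 3142 RPM in the heat-stress library, with log2 ratios from 2.31 to 3.98. Runs of 3 lay on chromosome 4, with 123.1 RPM in the control library and 451 RPM in the heat-stress library, and on chromosome 12, with 52.1 and 202 RPM. The 184 lower models formed 7 pairs, at the upper end of the central 95% of shuffles, 0 to 7. All 7 were on the same strand, above the central 95% of 0 to 4 for same-strand pairs, though 7 of 10000 shuffles had as many, and 0 were on opposite strands. Reads were fractional in both members of 3 of the 7, against a mean of 0.283 in the shuffles (central 95% of 0 to 2, with 24 of 10000 having as many). Their longest run was 3 models on chromosome 9, which had 282 RPM in the control library and 68.3 RPM in the heat-stress library. Pairs on the same strand made up 24 of the 35 higher pairs, against 8.71 in the shuffles. Pairs on opposite strands were 11, within the central 95% of 3 to 14. Reads were fractional in both members of 11 of the 35 higher pairs, against a mean of 1.596 in the shuffles. The excess was absent among models with whole-number reads when pairs of equal peak heights were left out. These formed 7 higher pairs, inside the central 95% of 5 to 17.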

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

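The values below come from deposited data that the comparison of RPM between gene models did not use. They differed little between the 2 libraries, and no difference has a replicate check. In the heat-stress library 28.9% of mapped reads lay outside the listed gene models, against 27.5% in the control library. The highest peak of reads was higher than the model's own reads in 1.47% of the models listed in the heat-stress library (348 of 23748). In the control library the share was nearly the same, at 1.42% (325 of 22893). Of 21 models past the filter with a peak above their reads, 7 had a model within 10 places in identifier order with the same peak height in both libraries. All 7 were on the same strand as that neighbour, and 2 of 1000 other models had such a neighbour. Of the 2-fold higher models 1, and of the 2-fold lower models 1, had a peak above their reads. No biological explanation was tested for these values.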

How the results depend on the processing

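The counts of 441 higher and 187 lower models stayed within 1.5 times their value with a pseudocount of 0.1, with no filter, with the median ratio, trimmed mean or gene-model read scalings, without models whose peak was above their reads, and with the heat-stress reads thinned to the control total. Their ranges over these settings were 328 to 636 higher and 186 to 266 lower models. A pseudocount of 5 RPM gave 267 and 112, a filter of 20 RPM gave 248 and 115, and a 4-fold threshold gave 87 and 9 (77 and 12 with the median ratio scaling), since each is stricter by construction. With only models of whole-number reads, 296 models were higher and 116 lower, from fewer models tested. The split was 55.7% higher with the median ratio, 55.2% with the trimmed mean and 73.2% with the gene-model scaling, which let 12340 models past the filter, against 70.2% as reported. The other pseudocounts and scalings are the settings that can move a single ratio, while filters can remove a model. Solyc09g089540.2 was removed by the filter of 20 RPM, and it and Solyc12g040790.1 by keeping only whole-number reads, where the lowest log2 ratio was -2.41 in another model. Of their 20 log2 ratios of the 4 named models 18 moved by less than the counting interval and 2 by more, both with a pseudocount of 5, and none changed sign. That pseudocount reversed the order at both ends, with Solyc04g014480.2 at 4.84 above Solyc01g103920.2 at 4.83 and Solyc12g040790.1 at -2.58 below Solyc09g089540.2 at -2.27. With a pseudocount of 0.1 and with the gene-model scaling Solyc04g014480.2 was at rank 3. Removing models with shared reads, those with peaks above reads, thinning, the gene-model scaling, the 4-fold threshold with the median ratio and both matchings on version were chosen after seeing the data. Version-matched lists drawn from all chromosomes gave percentiles of 57.6 and 64.4 for chromosomes 11 and 12, but most version 1 models in those pools are models of chromosomes 10 to 12. Summing rows per gene changed nothing because no identifier was repeated. The alternatives for gene lists, for their share of the library and without the chaperone lists were not run, because the identifiers could not be joined to descriptions. No paired analysis was possible because each group had 1 library. Requiring a counting interval that excludes 1 removed no call, which the filter and the threshold make near certain. Depth limits models near 5 RPM most, where 58 and 69 reads stand behind a value, and the spread between replicates is unknown.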

Other observations

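All patterns below were noticed in the data. The tests of the scaling and of identifier versions were chosen after their results were seen, and those of neighbouring models after the pattern was seen but before their own results. Models listed in 1 library only were all weakly expressed. The 2022 models listed in the heat-stress library alone reached at most 3.07 RPM and the 1167 listed in the control library alone at most 0.607 RPM. Counting models with at least 1 read after rounding, the control library had 22201 and the heat-stress library 22989, or 22628 ± 18.7 (SD over 100 draws) when thinned to the control's mapped reads. The share of a model's reads in its highest peak differed little for most models. Over 8945 models with at least 100 reads in both libraries and no peak above their reads in either, the highest peak held a median of 25.4% of a model's reads in the control library and 24.7% in the heat-stress library. In 56 models this share was at least 10 percentage points higher in the heat-stress library and in 110 at least 10 points lower. These shares carry no counting interval and were not recomputed at equal depth, and the heat-stress library was the deeper one. The counts of 56 and 110 therefore do not show a shift between the libraries.

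Chromosomes 10 to 12 held fewer reads than their number of listed models would give. Models with a mean of at least 5 RPM made up 32.6% of those listed on chromosome 10, 27.0% on chromosome 11 and 25.5% on chromosome 12, against 48.0% to 53.7% on chromosomes 1 to 9. Of the 356 version 2 models of chromosome 10, 61.0% were past 5 RPM, with a lower bound of 55.7%, and version 2 models of chromosomes 1 to 9 gave 62.5% to 64.3%. This decides neither for nor against a low expression of all genes on chromosome 10 or fewer reads being collected by version 1 models, because version goes with expression elsewhere too. On chromosomes 1 to 9 version 1 models were past 5 RPM in 14.2%, against 25.1% on chromosome 10 and 25.7% on chromosomes 10 to 12, so the version 2 models are not a fair sample of the genes of a chromosome. In version 1 models past the filter the highest peak also held more of the control library's reads. The median was 46.0% on chromosomes 10 to 12 against 25.1% in version 2 models there. Chromosomes 1 to 9 gave 43.5% and 25.1%, so this difference goes with version and is not particular to chromosomes 10 to 12. On chromosomes 11 and 12 the version 2 models are 11, of which 100% were past 5 RPM, and they decide nothing for the same reason. A candidate explanation is that version 1 models stop short of the transcript's 3' end, where all MACE reads lie, so that genes of these chromosomes may be undercounted in both libraries. This was not tested, because no gene structures were used here.

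The excess of neighbouring higher models is a pattern for which a shared response of tandem gene copies may be the biological source, and no gene names were at hand to test it. Like abundance of neighbours was argued against, since the 35 pairs exceeded the central 95% of shuffles within 10 classes of abundance (10 to 25). Reads divided between near-identical models stay open. Among models with whole-number reads, with pairs of equal peak heights also left out, there were 7 higher pairs. This was inside the central 95% of shuffles, 5 to 17 (1 lower pair, 0 to 5). The 24 higher pairs with at least 1 whole-number member were at the upper end of theirs, 8 to 24. Tandem copies are also the models most likely to share reads, so this does not separate the explanations. Transcripts running into the next model on the same strand also stay open, because the 11 opposite-strand pairs showed no excess.

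The surplus of higher over lower models depends in part on the scaling to all mapped reads. With a median ratio of 1, 2-fold higher models were 1.26 times as many as lower ones, against 2.36 times as deposited and 2.73 times when scaled to the reads in gene models. The value of 1.26 lies between the bounds of 1.2 and 1.5 for a decision, which were set after the result was seen. With the median ratio scaling, models 4-fold higher were still 6.42 times as many as those 4-fold lower (77 and 12). The factor of 1.08 moves only models close to the threshold, so it could hardly remove a surplus of 87 over 9. This count therefore cannot weigh a larger scaling error. A response to the heat treatment that the labels name may account for the 4-fold differences. So may any other difference between the 2 libraries, such as the move to the growth chamber or the time of sampling. The design cannot separate them.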
